A study of Actinidia chinensis with 12 samples.

How the data were processed

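RNA from ripened kiwifruit of the cultivars Jinyan and Hongyang was sequenced in 12 libraries, 3 from each of 4 groups: Jinyan whole fruit, Jinyan flesh core, Hongyang whole fruit and Hongyang flesh core. Per the labels' protocols, total RNA was extracted with CTAB, poly(A) RNA was selected with oligo(dT) and fragmented, cDNA was primed with random hexamers, and paired-end libraries were sequenced on either of a pair of Illumina HiSeq models. Which model read which library is not given in the sources used here, so a sequencing batch could not be examined. The protocol names no strand-marking step, so reads of overlapping or antisense genes cannot be told apart in these counts.

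The authors' deposited table holds raw counts per gene, as whole numbers, for 39040 gene identifiers with the prefix Achn, with 1 column per library and no pooling. Reads were trimmed with Trimmomatic 0.36 and aligned with HISAT2 2.1.0, per the submitters' processing notes. The counting program, the genome build, the annotation and the treatment of reads that align to several genes are not given in the sources used here. Counts of gene copies that share sequence are therefore uncertain. Column names were matched to samples through the description label. The deposited counts summed to between 1888744 and 21222578 per library. Of all identifiers, 8533 had 0 counts in every library. Even numbers were in excess among low counts: they made up 56.2 to 60.3% of the counts from 1 to 20, and genes with a count of 2 outnumbered genes with a count of 1 in each library (1142 against 366 in Jinyan whole fruit replicate 1). Counting both reads of a pair would give such an excess, in which case counting error is understated. Reads are not independent molecules, so intervals and limits from 0 counts cover counting error only.

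The table gives identifiers alone, and no genome or gene-name table was used here. Lists of gene product names drawn up in advance (pigment, sugar, acid, ascorbate, cell wall and hormone genes, and markers of seed, cuticle, chloroplast and vascular tissue) could not be matched to identifiers and were not tested, and neither coordinates nor functions are given.

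Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (22199 genes with 99.9% of all counts), scaled by TMM factors, and fitted with 1 quasi-likelihood model of 4 group means over all 12 libraries (estimateDisp, glmQLFit, glmQLFTest, default settings). Contrasts gave Hongyang minus Jinyan in each tissue, core minus whole fruit in each cultivar, and the interaction, which is the Hongyang tissue difference minus the Jinyan tissue difference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes were derived from the F statistic, as the absolute log2 fold change over its square root. Where a group has 0 counts they depend on the prior count. CPM denotes counts scaled by TMM-adjusted library size, as edgeR's cpm gives them. The classes of genes without reads and the alternative filter at a minimum mean of 5 CPM used library totals without TMM factors instead. All groups shared 1 estimate of spread although the biological coefficient of variation, estimated within each group, was 0.164 in Jinyan whole fruit, 0.236 in Jinyan core, 0.547 in Hongyang whole fruit and 0.243 in Hongyang core. Tests involving Hongyang whole fruit therefore borrowed precision from tighter groups.

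The groups, tests, main alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 5 genes with the largest log2 difference in each direction, or 2 where identifiers carry no names, as here, among called genes with a mean of at least 5 CPM in 1 of the groups compared and, outside the interaction, no overlap between the libraries of those groups. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the 3 libraries of that group, the smaller of the bound from the mean CPM and that from counts summed over the other group. Leaving out a library of a group at 0 lowers such a bound by construction, since fewer counts stand behind the 0. Per-library measures (genes detected after thinning every library to the smallest total, and the share of counts in the 10 most abundant genes) were compared with two-sided exact permutation tests, 8 in all, with Benjamini-Hochberg adjustment; with 3 libraries against 3 the smallest p is 0.1. No label says that replicates came from separate fruits, trees or pools, so p-values measure the spread between these libraries only. No 2 libraries of a group matched within sampling noise (chi-square per degree of freedom of 6.1 to 138.1).

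The fit was tested on data simulated from these libraries with 100 genes changed 4-fold and 100 changed 2-fold in 1 group. The simulated groups shared 1 mean and 1 spread per gene, and the changed genes had at least 5 CPM over all libraries. Of these, 91% of genes changed 4-fold and 11% of those changed 2-fold were recovered for the cultivar difference in whole fruit. The recoveries were 92% and 26% for the cultivar difference in core, 93% and 16% for the tissue difference in Jinyan, 92% and 14% for that in Hongyang, and 52% and 1% for the interaction. Each simulated fit gave at most 6 false calls. Since the simulated spread was equal between groups, these figures do not cover the wider spread of Hongyang whole fruit.

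The alternatives fixed in advance were RLE scaling, no low-count filter, a minimum mean of 5 CPM, DESeq2 1.42.0, a replicate block, a fit of the 6 libraries compared alone, and leaving out each library. Library totals without scaling factors, thinning to equal depth, halved counts and limma 3.58.1 voom with sample weights were added after seeing the data.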

Results

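The transcriptomes of ripened fruit of 2 kiwifruit cultivars, Jinyan and Hongyang, were compared in whole fruit and in the flesh core, with 3 libraries per group. Hongyang is a red-fleshed and Jinyan a yellow-fleshed cultivar. The labels call the non-core samples whole fruit, whereas the series design speaks of the fruit periphery; the label is used throughout. Library totals ran from 6870519 to 21222578 counts, except for Hongyang whole fruit replicate 3 with 1888744. Of 39040 gene identifiers, 22199 carried enough counts to be tested. The identifiers are not paired with gene names in the table, so genes are given by identifier.

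Replicates within Jinyan whole fruit, Jinyan core and Hongyang core correlated at Spearman rho of 0.966 to 0.980, and Jinyan core correlated with Jinyan whole fruit at 0.897 to 0.926. Between the cultivars, the cores correlated at 0.869 to 0.896. These correlations are across genes, which are not independent replicates. Hongyang whole fruit was the exception among the groups. Its replicates 1 and 2 correlated at 0.949, its replicates 1 and 3 at 0.896 and its replicates 2 and 3 at 0.833, while replicate 2 reached 0.955 with a Hongyang core library.

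**Figure D1:**
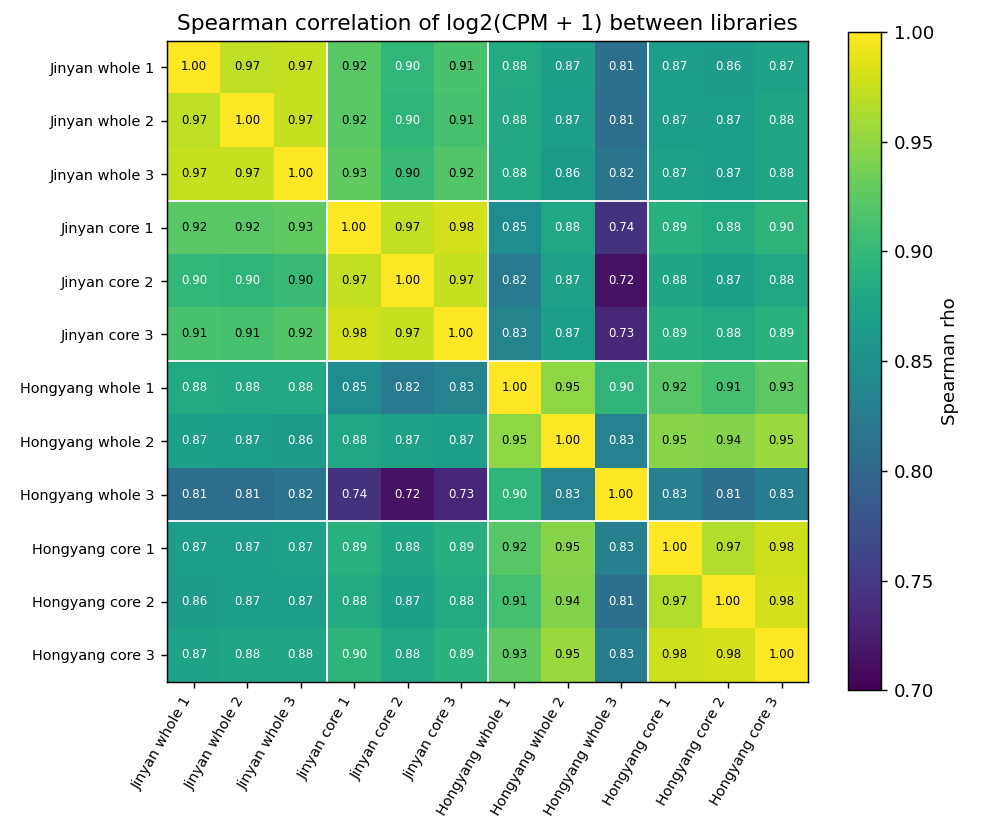
Spearman correlation of log2(CPM + 1) across the tested genes for each pair of the 12 libraries, with white lines between the 4 groups. The blocks on the diagonal lie at 0.966 to 0.980 except for Hongyang whole fruit, where replicate 3 correlates at 0.833 and 0.896 with its group.

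The most abundant gene, Achn022471, singled out after its values were seen, took 7.51% ± 0.73 (SD, n = 3) of counts in Jinyan whole fruit and 10.4% ± 2.1 (SD, n = 3) in Jinyan core. Its share was 8.13% ± 2 (SD, n = 3) in Hongyang whole fruit and 9.25% ± 0.74 (SD, n = 3) in Hongyang core, and it passed the edgeR test in none of the 5 comparisons (adjusted p of 0.13 to 0.92). At equal depth, 21690 ± 258 (SD, n = 3) genes were detected in Jinyan whole fruit and 20030 ± 458 (SD, n = 3) in Jinyan core. The corresponding numbers were 20910 ± 1500 (SD, n = 3) in Hongyang whole fruit and 21750 ± 135 (SD, n = 3) in Hongyang core. The Jinyan libraries of the 2 tissues did not overlap, and neither did the cores of the 2 cultivars, each with an exact permutation p = 0.1, the smallest that 3 against 3 allows, and an adjusted p = 0.2. The 10 most abundant genes held 20.5% ± 0.721 (SD, n = 3) of counts in Jinyan whole fruit against 26.7% ± 3.73 (SD, n = 3) in Jinyan core and 27.0% ± 2.37 (SD, n = 3) in Hongyang whole fruit, both with an exact permutation p = 0.1 and an adjusted p = 0.2.

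The design asks how the cultivars differ. In whole fruit, 5502 genes (24.8% of those tested) differed between Hongyang and Jinyan by edgeR, 3041 higher in Hongyang and 2461 lower. At least 2-fold differences were fitted for 2343 of the higher and 1738 of the lower genes, and at least 8-fold differences for 623 and 480. Achn288361 stood at 1140 ± 697 CPM (SD, n = 3) in Hongyang and had 0 counts in the 3 Jinyan libraries, at least 10100-fold higher (adjusted p = 1.6e-05). Achn328711 stood at 67.2 ± 25 CPM (SD, n = 3) in Hongyang, also against 0 counts, at least 598-fold higher (adjusted p = 4.6e-06). In the other direction, Achn125851 stood at 2670 ± 667 CPM (SD, n = 3) in Jinyan against 5 counts over the 3 Hongyang libraries, with a log2 fold change of -14.06 ± 0.92 (SE; adjusted p = 1.3e-06). All 5 of these counts lay in Hongyang replicate 1, and the fitted value was -18.10 without that library, when it is no bound, and -13.07 without Hongyang replicate 2. Achn277931 stood at 37.7 ± 3.68 CPM (SD, n = 3) in Jinyan and had 0 counts in Hongyang, at least 427-fold lower there (adjusted p = 1.7e-05). The count of called genes was 2833 when only these 6 libraries were fitted, and 3637, 3619 and 3516 without Jinyan whole fruit replicate 1, 2 and 3. It was 6748 without the shallow Hongyang replicate 3, and without Hongyang replicate 2 the direction of the split turned, with 3047 higher and 3172 lower. The bound of Achn288361 was 6400-fold without Hongyang replicate 2 and 6010-fold without Jinyan replicate 3, that of Achn328711 was 356-fold without Jinyan replicate 3, and that of Achn277931 was 256-fold and 202-fold without Hongyang replicate 1 and 2.

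In the flesh core, 6650 genes (30.0%) differed between the cultivars, 3554 higher in Hongyang and 3096 lower. At least 2-fold differences were fitted for 2865 higher and 2039 lower genes, and at least 8-fold differences for 874 and 409. Of the genes named for whole fruit, 3 were also named here: Achn288361 at 3000 ± 1720 CPM (SD, n = 3) in Hongyang against 0 counts in Jinyan, at least 39400-fold higher (adjusted p = 5.3e-06), Achn328711 at 106 ± 21.3 CPM (SD, n = 3), at least 1510-fold higher (adjusted p = 1.4e-06), and Achn125851 at 4260 ± 2090 CPM (SD, n = 3) in Jinyan against 0.567 ± 0.447 CPM (SD, n = 3) in Hongyang, a log2 fold change of -12.83 ± 0.81 (SE; adjusted p = 4.5e-07). Achn365111 had 41.6 ± 15.2 CPM (SD, n = 3) in Jinyan core and 0 counts in Hongyang core, at least 752-fold lower there (adjusted p = 1.6e-06), and it had 0 counts in Hongyang whole fruit as well. Leaving out 1 core library gave 4730 to 5295 genes, and a log2 fold change of -13.79 for Achn125851 without Hongyang replicate 2. Without Jinyan replicate 1 and 3, the bounds were 24400-fold and 26000-fold for Achn288361 and 932-fold and 995-fold for Achn328711, and without Hongyang replicate 2 and 3 they were 469-fold and 464-fold for Achn365111. The split by direction rested on the scaling: with library totals only, 72.8% of called genes were higher in Hongyang against 53.4% with TMM, and the median gene lay at 0.41 instead of 0.11 on the log2 scale. At equal depth the split turned to 1947 higher and 2034 lower.

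The cultivar differences of the 2 tissues were measured in separate libraries. Across genes, the log2 fold changes in whole fruit and core correlated at Pearson r = 0.618 and Spearman rho = 0.579; genes are not independent replicates. In both tissues 1682 genes were higher in Hongyang and 1516 lower, where independent lists of these sizes would share 487 and 343, and 69 genes were called in opposite directions. Both lists came from 1 fit with a shared estimate of each gene's spread, which can by itself raise the overlap above the independent figures. Of the genes higher in Hongyang whole fruit, 90.3% had a positive fold change in core, with a median of 1.05 against 1.5 in whole fruit. Of the genes lower there, 88.8% had a negative one. Both sets were called on the whole fruit libraries, which enlarges the median in whole fruit. A further 2235 genes passed the test in whole fruit but not in core, and 134 of these passed the interaction test. Of 3383 genes that passed in core but not in whole fruit, 227 did. Reads of alleles that differ from the reference and fail to align would lower a gene in both tissues of a cultivar. Agreement between the tissues therefore does not separate differences in expression from lost alignments, since counts hold no sequence. The same limit applies to the genes named for the cultivar differences, including those without counts in a cultivar.

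**Figure D2:**
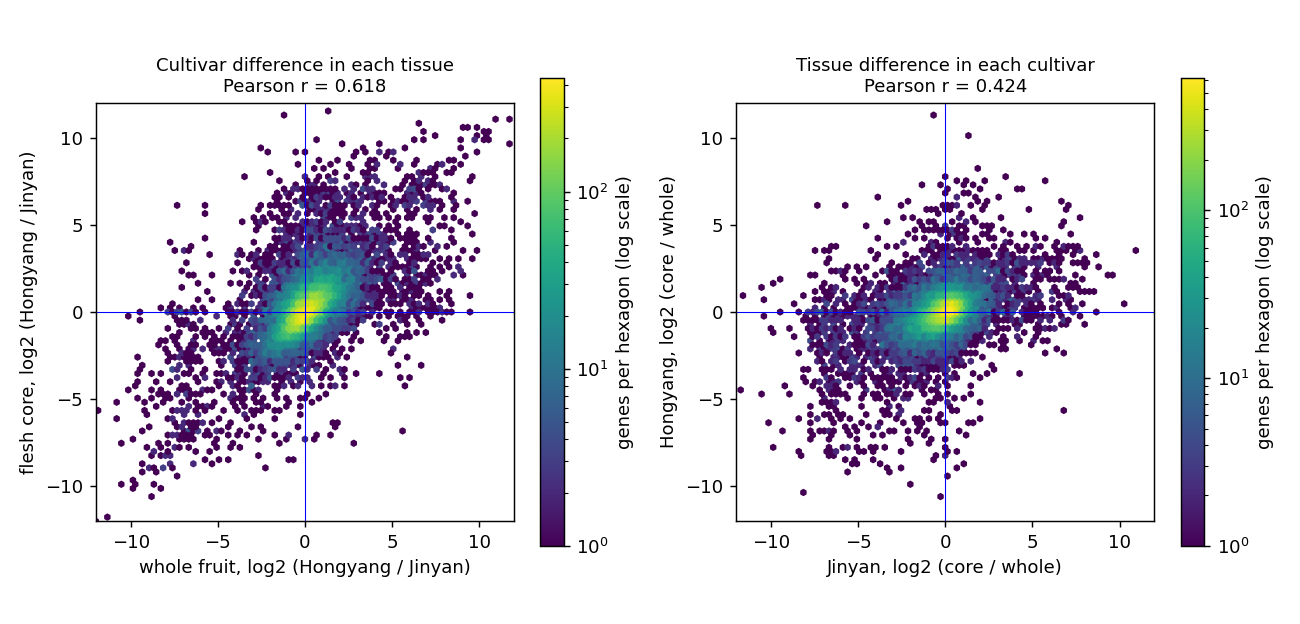
Log2 fold changes of the tested genes, Hongyang over Jinyan in whole fruit (x) and core (y) on the left, and core over whole fruit in Jinyan (x) and Hongyang (y) on the right, with colour giving genes per hexagon on a log scale. The cultivar differences lie closer to a common line (r = 0.618) than the tissue differences (r = 0.424); 6 genes fall outside the left axes.

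Some genes had no reads at all in 1 cultivar. Of all identifiers, 113 had 0 counts in the 6 Jinyan libraries and a mean of at least 1 CPM in Hongyang, and 99 of these were seen in both Hongyang tissues. The reverse held for 60 genes, 54 of them seen in both Jinyan tissues. The Jinyan-absent genes made up 65.3% of both classes (95% exact binomial interval 57.7 to 72.4%), although genes are not independent. At a mean of at least 5 CPM the numbers were 18 and 7.

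The design also asks how the core differs from the whole fruit. In Jinyan, 3688 genes (16.6%) differed, 1809 higher in the core and 1879 lower. Large differences were more often lower in the core: 1623 of the lower genes and 1058 of the higher genes differed at least 2-fold, and 552 against 263 at least 8-fold. Achn308791 stood at 18.7 ± 3.98 CPM (SD, n = 3) in the core against 0 counts in whole fruit, at least 167-fold higher (adjusted p = 9.3e-04), and Achn071231 at 10.6 ± 8.79 CPM (SD, n = 3), at least 86.9-fold higher (adjusted p = 0.0046). Achn008781, at 32.6 ± 10.2 CPM (SD, n = 3) in whole fruit, had 0 counts in the core, at least 465-fold lower (adjusted p = 0.0042), and so did Achn233741, at 29.8 ± 24.4 CPM (SD, n = 3) in whole fruit and at least 409-fold lower in the core (adjusted p = 0.0029). With limma voom and sample weights Achn233741 did not pass (adjusted p = 0.053, and 1.6e-10 to 0.053 over all alternatives). With library totals only, 13.8% of called genes were higher in the core against 49.1% with TMM, the median gene lying at -0.40 instead of 0.04, so the balance of directions rested on the scaling. The count was 6878 when only these 6 libraries were fitted. It was 1572, 1382 and 1578 without whole fruit replicate 1, 2 and 3, and 1386 and 1701 without core replicate 2 and 3. At equal depth it was 1768, with 15158 genes tested. More genes were higher than lower without core replicate 1, 2 or 3 (51.0%, 52.8% and 54.0% higher), at a mean of at least 5 CPM (52.8%), at equal depth (53.1%), with halved counts (50.7%) and with voom (53.4%). Without whole fruit replicate 3 the bounds were 99.1-fold for Achn308791 and 51.7-fold for Achn071231, which had 49.3-fold without core replicate 2. Without core replicate 1 and 3 they were 288-fold and 307-fold for Achn008781 and 253-fold and 270-fold for Achn233741, which had 222-fold without whole fruit replicate 2.

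In Hongyang, 1039 genes (4.68%) differed between core and whole fruit, 554 higher in the core and 485 lower, in a fit whose spread was shared with the tighter groups. When the 6 Hongyang libraries were fitted alone, 76 genes passed, 14.5% of them higher in the core. Achn333721 stood at 21.6 ± 8.27 CPM (SD, n = 3) in the core against 0 counts in whole fruit, at least 248-fold higher (adjusted p = 1.5e-04), and Achn217331 at 10.7 ± 0.26 CPM (SD, n = 3), at least 122-fold higher (adjusted p = 0.010). Achn142621, at 14.5 ± 8.37 CPM (SD, n = 3) in whole fruit, and Achn379101, at 11.8 ± 4.89 CPM (SD, n = 3), had 0 counts in the core, at least 267-fold and 217-fold lower (adjusted p = 0.0048 and 2.1e-04). Achn379101 was also lower in the Jinyan core, at 0 counts against 2.66 ± 0.353 CPM (SD, n = 3) in Jinyan whole fruit (adjusted p = 0.0014). The count rested on single libraries: it was 175 without whole fruit replicate 1 and 4370 without whole fruit replicate 2, and 639, 266 and 360 without core replicate 1, 2 and 3, while without the shallow replicate 3 it was 1161. The direction of the split turned without whole fruit replicate 1 (55 higher and 120 lower), without whole fruit replicate 3 (507 and 654) and without core replicate 2 (122 and 144), and 57.5% were higher without whole fruit replicate 2. Without whole fruit replicate 1 and 2 the bounds were 149-fold and 117-fold for Achn333721 and 73.3-fold and 57.7-fold for Achn217331, and without core replicate 2 and 3 they were 167-fold and 165-fold for Achn142621 and 135-fold and 134-fold for Achn379101. Achn217331 lost its call without whole fruit replicate 1 (adjusted p = 0.062, and 2.3e-05 to 0.062 over all alternatives), and with library totals only 35.1% of called genes were higher in the core against 53.3% with TMM, the median gene lying at -0.19 instead of 0.01.

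**Figure D3:**
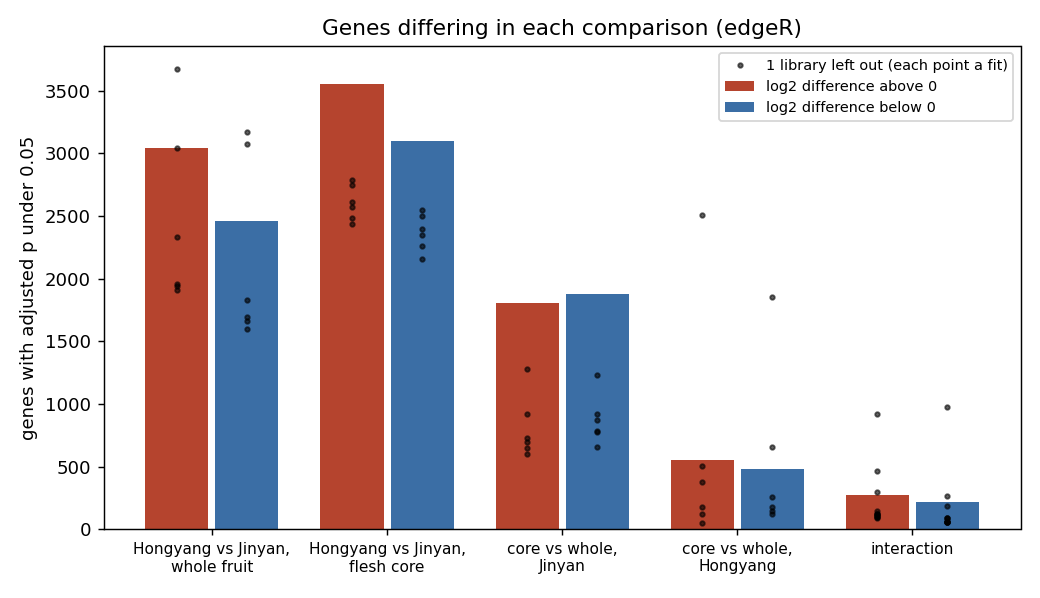
Genes with an adjusted p under 0.05 in each comparison (bars, all 12 libraries), split by the sign of the log2 difference (Hongyang minus Jinyan, core minus whole fruit, Hongyang minus Jinyan tissue difference), with points for fits that leave out 1 library of the groups compared. The bars are 3554 and 3096 genes for the cores, 554 and 485 for the Hongyang tissues and 277 and 223 for the interaction.

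Of the genes higher in the Jinyan core, 76.7% had a positive fold change in Hongyang, with a median of 0.35 against 1.10 in Jinyan. Of the genes lower in the Jinyan core, 75.1% had a negative one, with a median of -0.53 against -1.88. The genes were called on the Jinyan libraries, which enlarges the Jinyan medians. A smaller median in Hongyang does not by itself show smaller effects. Both cultivars called 182 genes higher and 166 lower in the core, against 45 and 41 for independent lists, and 34 genes in opposite directions. Here too the shared estimate of spread can raise the overlap. The correlation across genes was r = 0.424 (Spearman rho = 0.393), and it was 0.305 without Hongyang whole fruit replicate 3. The mean of log2(CPM + 1) over the 1809 genes higher in the Jinyan core minus that over the 1879 lower genes was 0.472 ± 0.057 (SD, n = 3) in Jinyan whole fruit and 3.1 ± 0.21 (SD, n = 3) in Jinyan core, where the genes were chosen. In Hongyang, where they were not, it was 1.71 ± 0.042 (SD, n = 3) in core and 0.745 ± 0.72 (SD, n = 3) in whole fruit, with no overlap (exact permutation p = 0.1, the smallest possible). The Hongyang whole fruit replicates 1, 2 and 3 stood at 0.618, 1.52 and 0.0998.

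**Figure D4:**
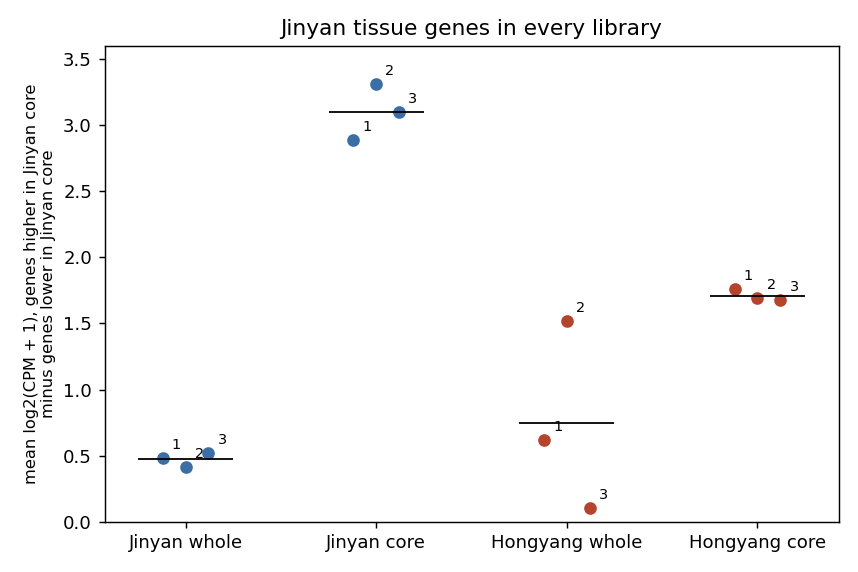
Mean log2(CPM + 1) of genes higher in the Jinyan core minus that of genes lower in the Jinyan core, per library (points, numbered by replicate) with group means (lines). Hongyang whole fruit spreads from 0.0998 to 1.52, while the Hongyang cores sit between 1.68 and 1.76.

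Whether the tissue difference depended on the cultivar was tested by the interaction, which called 500 genes (2.25%), 277 with a larger log2 difference of core minus whole fruit in Hongyang and 223 with a smaller one. The fitted tissue effects had opposite signs for 414 of the 500. Without regard to sign, the fitted tissue effect was larger in Jinyan for 324 genes and in Hongyang for 176. Of the 500, 316 passed the tissue test in Jinyan and not in Hongyang and 116 in Hongyang and not in Jinyan. Another 42 passed in both and 26 in neither. Achn233741 and Achn142621, named above for Jinyan and Hongyang, passed the interaction test: Achn233741 stood at 22 ± 23.7 CPM (SD, n = 3) in Hongyang core and 12.2 ± 4.47 CPM (SD, n = 3) in Hongyang whole fruit, and Achn142621 at 1.84 ± 1.86 CPM (SD, n = 3) in Jinyan core and 2.28 ± 2.17 CPM (SD, n = 3) in Jinyan whole fruit. Achn333721 stood at 1.21 ± 0.73 CPM (SD, n = 3) in Jinyan core and 2.02 ± 0.748 CPM (SD, n = 3) in Jinyan whole fruit. Achn105791 stood at 25.4 ± 8.39 CPM (SD, n = 3) in Hongyang whole fruit against 0.0502 ± 0.087 CPM (SD, n = 3) in Hongyang core, and at 0.393 ± 0.148 and 0.662 ± 0.221 CPM (SD, n = 3) in Jinyan whole fruit and core. The interaction count was 1899 without Hongyang whole fruit replicate 3 and 239 without replicate 1, 168, 150 and 183 without Jinyan whole fruit replicate 1, 2 and 3, 211, 160 and 214 without Jinyan core replicate 1, 2 and 3, and 157 and 192 without Hongyang core replicate 2 and 3. Achn142621 lost its call without Jinyan whole fruit replicate 2 (adjusted p = 0.062) and without Hongyang core replicate 2 (adjusted p = 0.051), with a range of 1e-06 to 0.1 over all alternatives, the highest at equal depth. Achn105791 lost its call at equal depth (adjusted p = 0.19, range 4.2e-12 to 0.19) and Achn233741 with limma voom (adjusted p = 0.081, range 3.5e-08 to 0.081). With library totals only, 78.9% of called genes had the larger signed difference in Hongyang, against 55.4% with TMM. The median gene lay at 0.23 instead of -0.02. The direction of the split turned at a mean of at least 5 CPM (254 and 293) and without Hongyang whole fruit replicate 3 (920 and 979).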

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

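The tests of the labels of Hongyang whole fruit replicates 2 and 3 and of the spread among the Hongyang whole fruit libraries were chosen after the values they rest on had been seen, and no outcome was set beforehand for replicate 3 minus replicate 1 or for the slopes of genes chosen on Jinyan replicate 1.

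The tissue difference depended on the cultivar for 500 genes by the interaction test, and for 150 to 1899 when 1 library was left out. The 4 genes named for it had fitted log2 differences, Hongyang tissue difference minus Jinyan tissue difference, of 12.45 ± 2.0 (SE) for Achn233741 (adjusted p = 0.010), 11.84 ± 1.2 (SE) for Achn333721 (adjusted p = 8.5e-04), -10.40 ± 1.9 (SE) for Achn142621 (adjusted p = 0.020) and -9.76 ± 0.93 (SE) for Achn105791 (adjusted p = 4.2e-04), all by edgeR. Achn071231, named for the Jinyan tissue difference, also passed, at -9.64 ± 2.1 (SE; adjusted p = 0.042). Each of these except Achn105791 has a group with 0 counts, so its fitted size depends on the prior count and is no bound. The SE is derived from that size, so for these genes it does not measure precision. The fit of Achn105791 rests on 2 counts in Hongyang core, both in replicate 1. Without Jinyan whole fruit replicate 2 and Hongyang core replicate 2 the value of Achn233741 was 11.59 and 11.03, without Jinyan whole fruit replicate 1 and Jinyan core replicate 1 that of Achn142621 was -11.55 and -9.14, and without Hongyang core replicate 1 and 3 that of Achn105791 was -12.06, set by the prior count because the group is then at 0, and -9.17. The call of Achn142621 was lost without Jinyan whole fruit replicate 2 (adjusted p = 0.062) or Hongyang core replicate 2 (adjusted p = 0.051) and at equal depth (adjusted p = 0.1), that of Achn105791 at equal depth (adjusted p = 0.19) and that of Achn233741 with voom (adjusted p = 0.081). Over all alternatives their adjusted p ranged from 1e-06 to 0.1, 4.2e-12 to 0.19 and 3.5e-08 to 0.081.

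The 3 Hongyang whole fruit libraries lay apart from one another, with replicate 3 at 1888744 counts, and low depth alone is argued against: thinned to the total of replicate 3, replicates 1 and 2 still correlated at 0.924, which exceeds the 0.886 between replicates 1 and 3 by 0.0378 as a mean of 10 draws. A wrong group label of replicate 3 is also argued against, since its best correlation with its own group exceeded that with any other group by 0.0655. For replicate 2 a wrong label stays open, with values on both sides: its highest correlation was 0.955 with a Hongyang core library against 0.949 within its group, but the cores correlated with one another at 0.966 to 0.980, its tissue position of 1.52 lay outside their range of 1.68 to 1.76, and each core library correlated best within its own group, which leaves no partner for an exchange. Different shares of core tissue remain a candidate explanation for replicate 2 lying apart and account for less of the distance between replicates 1 and 3: across 13401 genes, replicate 3 minus replicate 2 correlated with Jinyan whole fruit minus core at r = 0.474, and replicate 1 minus replicate 2 at 0.506, but replicate 3 minus replicate 1 at 0.298, which is 22.5%, 25.6% and 8.88% of the variance. A difference between fruits in ripening or quality stays open as untested.

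Fewer genes differed between tissues in Hongyang (1039) than in Jinyan (3688). The low depth of 1 Hongyang library is argued against as the whole cause, because with all libraries thinned to the smallest total the ratio of the counts was still 1.91. Whether the spread among the Hongyang whole fruit libraries contributes stays open: the ratio was 1.27 without replicate 2, 20.1 without replicate 1 and 5.53 without replicate 3 (6423 Jinyan and 1161 Hongyang genes), but leaving out replicate 2 moves the group mean as well as the spread, and the spread is shared by both tissue tests. The counts also moved with the fit. They were 7698 in Jinyan and 6115 in Hongyang with limma voom, and 5244 and 2503 with DESeq2. Each cultivar fitted alone gave 6878 and 76. Voom gave Hongyang whole fruit replicates 2 and 3 weights of 0.228 and 0.31, which also moves the group mean. Smaller tissue effects in Hongyang may contribute as well. The slope of the Hongyang on the Jinyan fold change was at most 0.418 in the fits without 1 Hongyang whole fruit library. That slope was taken over genes called in Jinyan, a choice that by itself lowers it. For 3710 genes chosen on Jinyan replicate 1, the slope was 0.795 in the held-out Jinyan libraries and 0.376 in Hongyang (0.506 without whole fruit replicate 2), and core tissue in the whole fruit libraries would lower it just as a biological difference between the cultivars would.

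Genes without reads were more numerous in Jinyan (113) than in Hongyang (60). Depth is argued against, since thinning all libraries to the same total left a ratio of 1.82 ± 0.15 (SD over 10 draws) and at least 1.54 in each draw. Reads of Jinyan alleles that differ from the reference and fail to align cannot be told apart from genes that Jinyan lacks or does not express. The ratio of 1.88 in the counts as deposited is what either would give, and counts hold no sequence. For alleles of either cultivar, the same limit holds for the called cultivar differences and their agreement between tissues.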

How the results depend on the processing

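Library totals, equal depth, halved counts, voom and the leave-one-out correlations were chosen after seeing the data. RLE scaling, no filter, a minimum of 5 CPM, halved counts and library totals left each of the 5 counts of called genes within 1.5 times. Replicate numbers were not shown to pair the libraries (3 of 18 correlations over 0.1; in 8 of 18 a library correlated best with its own number); with a replicate block the counts were 5045 and 6437 for the cultivars in whole fruit and core, 3500 and 854 for the tissues in Jinyan and Hongyang, and 438 for the interaction. A fit of only the 6 libraries compared gave 2833 genes for the cultivars in whole fruit, 6878 for the Jinyan tissues and 76 for the Hongyang tissues. DESeq2 called 2503 genes for the Hongyang tissues and 1530 for the interaction. Equal depth gave 3981 genes for the cores, 1768 for the Jinyan tissues and 274 for the interaction, with fewer genes tested (15158). In the order of the report, limma voom with sample weights called 9458, 10553, 7698, 6115 and 2955 genes. Leaving out 1 library of the groups compared gave 3516 to 6748 genes for the cultivars in whole fruit. It gave 1382 to 2514 for the Jinyan tissues, 175 to 4370 for the Hongyang tissues and 150 to 1899 for the interaction. Without Hongyang whole fruit replicate 1, 2 and 3, which the Jinyan contrast does not hold, the Jinyan tissue count was 3521, 5566 and 6423. The correlation of cultivar differences was 0.718, and that of tissue differences 0.463, over genes of at least 5 CPM; leaving out 1 library, which let more low genes pass the filter, they ranged from 0.544 to 0.595 and from 0.305 to 0.416. Genes without reads numbered 18 in Jinyan and 7 in Hongyang at 5 CPM, and 228 and 134 at equal depth. At equal depth the interaction calls of Achn105791 (adjusted p = 0.19) and Achn142621 (0.1) were lost, and with voom both calls of Achn233741 (0.053 and 0.081). Of 144 leave-one-out values of the named genes, 141 kept their call. So did 114 of 114 under the other planned settings and 75 of 79 under the added ones, and none changed direction. These genes were chosen from the same data for large differences and, outside the interaction, for no overlap between libraries. Their stability is therefore largely set by that choice, and some of them enter for more than 1 comparison. The causes of the changes given in this paragraph were not tested. The planned tests of gene lists were not run, because no gene names were at hand.

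For the 4 comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. In fits of those 6 libraries, the real split called 2833, 9060, 6878 and 76 genes, and 1 of the 10 splits, the real one, called as many; the highest other split called 0, 0, 0 and 2. For the interaction, 2 of 60 splits drawn from 200 called as many as the real 500. Splits that mix the tissues of a cultivar put tissue differences into the spread and so hold calls down, and the share of splits does not settle whether chance is excluded. The other of the 2, with 2943 genes, exchanges the Jinyan tissues and, in Hongyang, whole fruit replicate 2 with core replicate 3. That split adds the tissue effects instead of subtracting them and points to the structure of the samples. Hongyang whole fruit replicate 2 is the library for which a wrong label stays open above.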

Other observations

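Abundant genes, a class formed after seeing the data from the 1000 genes with the highest mean CPM, were called more often in one direction than the other in the 4 comparisons below. Of these genes, 304 were lower and 97 higher in Hongyang whole fruit than in Jinyan, and 377 were lower and 78 higher in Hongyang core. With library totals only, these splits were 340 and 128, and 273 and 156. In the core against whole fruit, 74 were higher and 19 lower in Hongyang (68 and 40 with library totals only), and 211 were higher and 30 lower in Jinyan, where the split was 86 and 113 with library totals only, a scaling that moved the median of all genes from 0.04 to -0.40 on the log2 scale.

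Achn022471 held the most counts in all libraries but Hongyang whole fruit replicate 3, where Achn326791 did, with 6.31% of counts. The same gene held 0.965% and 0.114% in Hongyang whole fruit replicates 1 and 2, 0.105% to 0.469% in Hongyang core, 0.719% to 1.28% in Jinyan whole fruit and 0.0779% to 0.239% in Jinyan core. It was singled out after its values were seen.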
